A study of Rattus norvegicus with 6 samples.

How the data were processed

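RNA from plasma exosomes, small membrane vesicles pelleted from plasma by ultracentrifugation, was measured in Sprague-Dawley rats with subarachnoid haemorrhage (SAH), made by perforating the internal carotid artery from inside the vessel, and in sham-operated rats in which the artery was left intact. Per the labels' protocols, plasma was taken on day 3, total RNA was reverse transcribed from a thymidine-run primer with Cy3-labelled nucleotide, and each sample was hybridised to 1 array. The labels name 3 SAH and 3 sham biological replicates, each with its own array.

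Per the file headers, the scanner images were read with Agilent Feature Extraction, whose version is given as 10.7.1.1 in the submitters' processing notes. The deposited scanner values are spot intensity on a linear scale: a mean signal, a median local background, and a processed signal from which background was subtracted and spatial trends were removed, with no normalization between arrays per the file headers. The authors' deposited value table is on a log2 scale, as its values show against the scanner signal of the same arrays. Its Pearson correlation with the log2 processed signal ran from 0.990 to 0.999, and its column medians were 3.10 on all 6 arrays, with a shared minimum of 1.28. The method that gave the columns this common distribution is not given in the sources used here. No direction between groups enters that table, since each column is 1 array.

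Each array held 62976 spots, of which 1439 were control spots. The remaining 61537 spots carried 60148 probes of 60 nucleotides. Of these, 57102 had names beginning with rclstr and are called cluster probes here, and 3046 were named after CIRCpedia, a database of circular RNAs, and are called circRNA database probes. The gene name column repeated the probe name, the position column read unmapped, and no probe outside the controls carried a gene symbol. The reference table of 47357 rat genes holds names but no sequences, so it named none of the probes. The 43 gene lists and cell type marker lists set before the data were examined matched 0 probes, and the planned test of those lists (limma's camera) was not run.

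Control spots and spots marked as nonuniform or population outliers (63 to 98 noncontrol spots per array) were left out, and spots of one probe were averaged on the log2 scale. No noncontrol spot was saturated. On average 35.9% of the probes were well above background, so each array's 75th percentile was taken over the 10957 probes well above background on all 6 arrays and subtracted from the log2 processed signal. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which left 17158 probes. SAH was compared with sham with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. A screening count, not corrected for multiple tests, took probes with an unadjusted p under 0.05 and at least a 2-fold difference. Comparisons of single values used an exact permutation test, two-sided, whose smallest p with 3 against 3 is 0.1. A probe not well above background on any array of a group has only a bound on its fold: the brighter group's mean was set against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. This bound is between group means of the processed signal and carries no sampling error.

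Because no probe had a gene symbol, the rule set before the data were examined names up to 2 probes per class and direction, those with the smallest p. The 1 with the smallest p of each class and direction is named here, with its sequence. Rat Gapdh and Pgk1 control probes are given as checks. The fit was tested on simulated data with the noise level estimated from the 17158 probes. It recovered 1.49% of probes changed by 1 on the log2 scale, 76.1% of those changed by 2 and 100% of those changed by 3, with 8 calls among unchanged probes. The simulated noise was independent between arrays and between probes, and no simulated sham array was made to resemble SAH. The recovered shares therefore check the fit and do not give the power of the real comparison.

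Per the file headers, the arrays came from 2 slides, with sham replicate 1 alone on one and the other 5 arrays on the other, and all were scanned on 1 day. The alternatives were normexp background correction with offset 50, other scalings (the 75th percentile over all noncontrol probes, the median, quantile normalization), the deposited value table, no filter or a stricter filter on dim probes, other variance settings (trend and robust, array weights), the slide and the replicate number as blocks, and leaving out each array in turn. The normexp offset is added to every signal and by itself shrinks the log2 differences of dim probes. The number of arrays limits the precision of every value.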

Results

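The data were 6 single-colour arrays of plasma exosome RNA from rats on day 3, 3 after SAH and 3 after a sham operation. The study's design text gives a single comparison of these conditions. The share of the 60148 probes well above background was 29.8%, 39.8% and 25.6% on sham replicates 1, 2 and 3, and 34.9%, 33.3% and 52.2% on SAH replicates 1, 2 and 3. Mean probe numbers well above background were 24129 ± 6294 (SD, n = 3) in SAH and 19064 ± 4379 (SD, n = 3) in sham. The groups differed by 5065 probes (exact permutation test, two-sided, p = 0.4, smallest possible 0.1). Their values overlapped, since sham replicate 2, at 39.8%, lay above SAH replicates 1 and 2. Over 29 probes printed in several spots and well above background on all 6 arrays, the median SD between spots of one array ran from 0.21 to 0.33 on the log2 scale.

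Across the tested probes, which are not independent replicates, Pearson correlations between SAH arrays ran from 0.952 to 0.959, and those between sham arrays from 0.887 to 0.894. Sham replicate 2 correlated at 0.955, 0.939 and 0.950 with SAH replicates 1, 2 and 3. Sham replicates 1 and 3 correlated with the SAH arrays at 0.835 to 0.879. The first principal component held 49.3% of the variance, and sham replicate 2, at 11.3, lay nearer to the SAH arrays than to sham replicates 1 and 3.

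**Figure D1:**
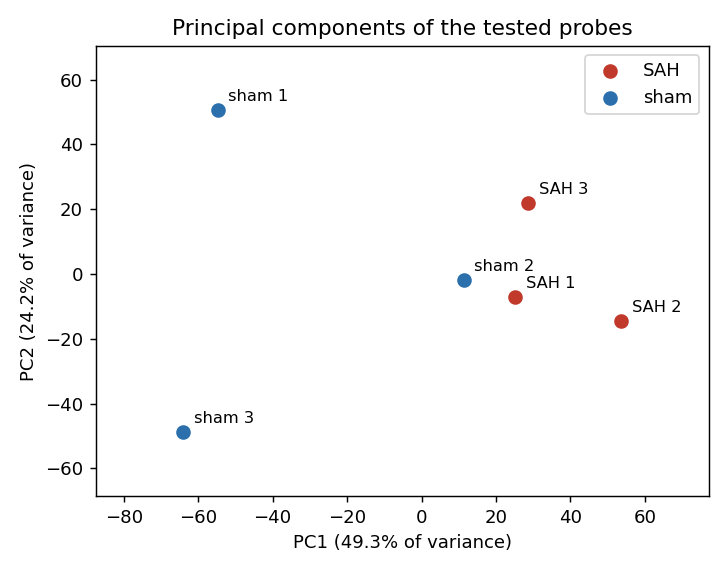
First and second principal components of the tested probes, with 49.3% and 24.2% of the variance on the axes and 1 point per array, coloured by group. SAH replicates lie at 25.2, 53.6 and 28.7 on the first component, sham replicate 2 at 11.3, and sham replicates 1 and 3 at -54.8 and -64.0.

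For the comparison of SAH with sham, no probe passed an adjusted p of 0.05. Of the 17158 tested probes, limma called 0 higher and 0 lower, with a smallest adjusted p of 0.126. At an unadjusted p under 0.05 there were 2527 probes, where 858 would be given by chance. The screening rule took 1203 probes, 1018 of them higher in SAH and 185 lower, so that 84.6% were higher. With no filter on dim probes the direction turned, with 1415 higher and 1759 lower (44.6% higher), and with normexp background correction the rule took 306 probes. In 835 of the 1203, the 3 SAH values did not overlap the 3 sham values. Over all tested probes 21.9% had no overlap, and in these more lay lower in SAH, 2115, than higher, 1636. Chance gives 10% on average, a rate that does not allow for probes that vary together or for the filter by group.

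The split between directions moved with the scaling, and 95.0% of screening probes were higher in SAH with the percentile taken over all noncontrol probes, 95.2% with the median and 92.3% with quantile normalization. The median difference of all tested probes was -0.15 under the scaling used and 0.04 with the percentile over all noncontrol probes, so differences are to be read against that shift. Without sham replicate 2, 663 probes passed the adjusted threshold, 648 higher in SAH and 15 lower, and the screening rule took 2073. Without sham replicate 3 the screening rule took 504 higher and 302 lower, and without SAH replicate 3 it took 770 higher and 524 lower. With the slide as a block, and within the slide that held both groups, 0 probes passed and 1167 met the screening rule, 1050 of them higher. Sham replicate 1 was alone on its slide, so both are the same fit as leaving out that array.

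**Figure D2:**
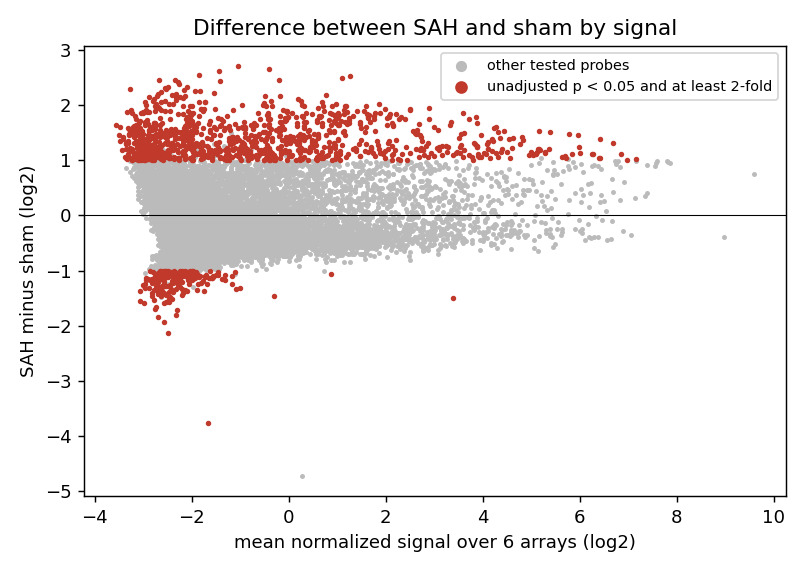
Difference between SAH and sham on the log2 scale against mean normalized signal over 6 arrays on the log2 scale, 1 point per tested probe, with the 1203 screening probes in red. Of these, 1018 lie above 0 and 185 below.

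Probes of both classes were found on either side. Among cluster probes, 16370 were tested and 1004 met the screening rule as higher in SAH and 178 as lower, which is 7.22% of those tested. Among circRNA database probes, which are named after a database of circular RNAs, 788 were tested and 14 met it as higher and 7 as lower, which is 2.66%. The cDNA was primed from a thymidine-run primer, and whether these probes measured circular RNA rather than linear RNA of the same sequence was not tested, which limits every value given for this class. Median differences were -0.15 for cluster probes and -0.20 for circRNA database probes. The median signal of circRNA database probes relative to that of cluster probes on the same array differed by -0.08 on the log2 scale between SAH and sham, lower on all 3 SAH arrays than on all 3 sham arrays (exact permutation test, two-sided, p = 0.1, the smallest possible). The nearest values, -0.0918 on SAH replicate 3 and -0.0911 on sham replicate 1, almost met, so the separation is slight.

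The cluster probe with the smallest p among those higher in SAH was rclstr_33320_1368_11, with the sequence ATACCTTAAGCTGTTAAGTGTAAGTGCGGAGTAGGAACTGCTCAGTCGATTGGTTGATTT. Its normalized signal was -2.12 ± 0.20 (SD, n = 3) in SAH and -4.42 ± 0.31 (SD, n = 3) in sham. It was well above background on 3 SAH arrays and 0 sham arrays, so its fold between group means has only a bound, at least 1.43. That bound carries no sampling error, and the probe did not pass the adjusted threshold (limma adjusted p = 0.126). The circRNA database probe was RNO_CIRCpedia_2212_9_16, with the sequence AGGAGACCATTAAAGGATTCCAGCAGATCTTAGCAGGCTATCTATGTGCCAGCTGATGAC. It measured -2.26 ± 0.57 (SD, n = 3) in SAH and -4.06 ± 0.74 (SD, n = 3) in sham. With 0 sham arrays well above background, the same kind of bound between group means was at least 1.30-fold (limma adjusted p = 0.268).

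Among probes lower in SAH, the cluster probe was rclstr_58600_375_24, with the sequence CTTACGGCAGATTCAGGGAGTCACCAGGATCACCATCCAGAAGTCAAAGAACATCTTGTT. Its signal was -3.22 ± 0.51 (SD, n = 3) in SAH, where 2 arrays were well above background, and -1.41 ± 0.16 (SD, n = 3) in sham, a log2 difference of -1.81 ± 0.32 (SE; limma adjusted p = 0.268). The circRNA database probe was RNO_CIRCpedia_6573_13_10, with the sequence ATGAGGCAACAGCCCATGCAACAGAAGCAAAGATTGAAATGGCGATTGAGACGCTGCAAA. It measured -3.55 ± 0.76 (SD, n = 3) in SAH, where 1 array was well above background, and -2.09 ± 0.24 (SD, n = 3) in sham, a log2 difference of -1.46 ± 0.38 (SE; limma adjusted p = 0.268). On these 4 probes the SAH and sham values did not overlap, and none passed the adjusted threshold. All 4 were dim, and with normexp background correction their log2 differences were 0.15, 0.03, -0.67 and -0.51 in the order given.

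The control probes for Gapdh and Pgk1, both enzymes of glycolysis, were the rat probes that carried a gene name. The 3′ Gapdh probe measured 4.46 ± 0.19 (SD, n = 3) in SAH and 4.57 ± 0.19 (SD, n = 3) in sham, a log2 difference of -0.11 (exact permutation test, p = 0.5) that became 0.08 with the percentile over all noncontrol probes or the median and 0.12 with normexp. It became -0.35 with quantile normalization and -0.25 with the deposited values, and was -0.0060 without sham replicate 3 and -0.0026 without SAH replicate 3. The 3′ Pgk1 probe measured -0.80 ± 0.31 (SD, n = 3) in SAH and -1.49 ± 0.47 (SD, n = 3) in sham, a log2 difference of 0.69 (exact permutation test, p = 0.2) that became 0.14 with normexp. The 5′ probes differed by 0.10 for Gapdh and -0.03 for Pgk1, both under the spread between replicates. Over the alternatives the former ran from -0.05 with the slide as a block to 0.29 with the percentile over all noncontrol probes or the median, and the latter from -0.15 with normexp to 0.16 with those scalings. The 3′ signal relative to the 5′ signal of Gapdh, which depends on how far reverse transcription reached, differed by -0.21 between SAH and sham (exact permutation test, p = 0.3). The same measure for Pgk1 differed by 0.72, the other way (exact permutation test, p = 0.3), with 0.65, 1.25 and 0.34 on SAH replicates 1, 2 and 3 and -0.37, 0.73 and -0.29 on sham replicates 1, 2 and 3, so that sham replicate 2 lay within the range of the SAH arrays.

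**Figure D3:**
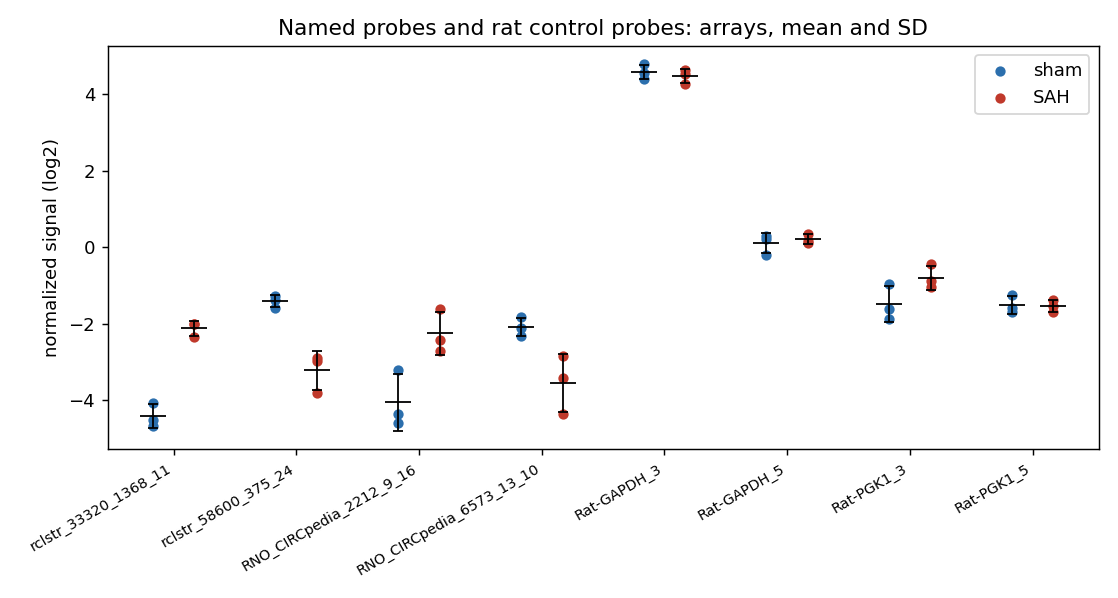
Normalized signal on the log2 scale of the 4 named probes and the 4 rat control probes, with 1 point per array, horizontal bars for group means and error bars for the SD of 3 arrays. The 3′ Gapdh probe shows means of 4.46 in SAH and 4.57 in sham, a difference of -0.11 that turned to 0.12 with normexp.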

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

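The tests of the slide, the scaling, a swap and a wrong label, and those of the direction among bright and dim probes, were chosen after the results were seen. The slide block, the other scalings and the fit without a filter were set beforehand as alternatives, but not as tests of a cause. The correlation of sham replicate 2 over bright probes was set as a test before its value was seen.

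Among 61 control probes not used in the comparison, 2 probes made for human Gapdh had a higher signal on every SAH array than on every sham array: the 3′ probe by 1.103 and the 5′ probe by 0.25 on the log2 scale. Chance gives this for 5% of probes, and 5 of the 61 were lower on every SAH array, among them the mouse Gapdh 3′ probe by -0.37. The 61 leave out the rat probes, the corner spots and the control 3xSLv1. Of those left out, DarkCorner and GE_BrightCorner were also lower on every SAH array, by -0.77 and -0.48. Under the scaling used, every control probe named E1A, DCP or ETG had a lower mean in SAH, with differences from -0.02 to -0.92. The rate of 5% does not allow for that shift. The rat Gapdh 3′ probe differed by -0.11, which ran from -0.35 with quantile normalization to 0.12 with normexp.

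Sham replicate 2 had a mean correlation with the other sham arrays minus that with the SAH arrays of -0.0586. A swap would put a sham sample among the SAH arrays. Each SAH array correlated more with its own group than with sham, by at least 0.0549, so none lay with the sham arrays. A sham sample that resembled the SAH arrays would give this too, so a swap is not excluded. Signal near background does not account for the value of -0.0586, since the difference was -0.0789 over the 4290 brightest tested probes. A single wrong label, such a swap, a sample from outside the series and variation between sham animals would all give the value of -0.0586. They cannot be told apart here. The mean correlation of sham replicate 2 with the other sham arrays, 0.890, was close to 0.890 and 0.893 for sham replicates 1 and 3.

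Among the tested probes, more were higher than lower in SAH under the screening rule, and with no filter on dim probes this turned to 44.6% higher (1415 against 1759). Outside the 4290 brightest tested probes, 74.8% of screening probes were higher with the filter and 35.8% without it, so the direction among the dimmer probes follows the filter, while within the 4290 brightest, whose median difference was -0.13, 477 of the 480 screening probes were higher (99.4%), which argues against signal near background for those 480. As the whole cause among the tested probes, the slide is argued against by 90.0% higher within the slide that held both groups, and the scaling by at least 92.3% higher under the other scalings. The real grouping gave 1203 screening probes, was the 1 of 10 splits with a count that large, and the highest other split gave 786, but 10 splits are too few for a share under 0.05; for the adjusted count, all 10 splits necessarily reached the real 0 (highest other 0), which says nothing about chance. A response to SAH, a difference in RNA quality and a difference in signal level between arrays stay open for those 480 probes. The 3′ to 5′ measure differed by -0.21 for Gapdh and 0.72 for Pgk1 (exact permutation p = 0.3 for each), in opposite directions, and decides none of these. The 75th percentile used for scaling was 56.8 and 63.8 on sham replicates 1 and 3 and 101 on sham replicate 2. It was 91.4, 98.9 and 131 on SAH replicates 1, 2 and 3. Signal level was not tested as a cause. The 663 calls without sham replicate 2 rest on leaving out the sham array that correlated more with SAH than with sham. Sham replicates 1 and 3, which then remain, had the lowest shares of probes well above background, 29.8% and 25.6%. Group and the number of probes well above background therefore cannot be told apart in that fit.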

How the results depend on the processing

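The alternatives were set before the data were examined, except the 4290 brightest tested probes, which was added afterwards. The count of 0 adjusted calls held under all but 3 alternatives. It became 1 (1 higher, 0 lower) with trend and robust settings, 416 (391 higher, 25 lower) with the replicate block, and 663 (648 higher, 15 lower) without sham replicate 2, so that leaving out each array gave 0 to 663 probes, 0 to 648 higher and 0 to 15 lower. Deviations of same-numbered arrays from their group means correlated at -0.02, 0.23 and -0.14, and those of unlike-numbered arrays at -0.21 to 0.23. No pairing by replicate number was seen, but so few arrays, whose deviations constrain each other, cannot exclude it. The cause of the added calls under the replicate block was not tested.

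The screening count of 1203 became 306 with normexp, 3174 with no filter on dim probes, 507 with only probes well above background on all 6 arrays and 471 in the 4290 brightest tested probes, where fewer probes were tested in the last 2. Leaving out each array gave 806 to 2073. The share higher in SAH, 84.6%, became 99.3% with normexp, 95.0% with the percentile over all noncontrol probes, 95.2% with the median and 99.4% in the 4290 brightest. It turned to 44.6% with no filter on dim probes, and ran from 59.5% to 90.0% on leaving out each array. For the turn with no filter, the values show the dimmer probes as its place: outside the 4290 brightest, 74.8% were higher with the filter and 35.8% without it. The scaling lowered spots at the signal floor in SAH, as with the control 3xSLv1, by -0.52. Its share in the turn and the other causes were not tested.

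The difference in probes well above background kept its direction under each alternative, from 1442.5 to 7487.8 probes on leaving out each array. The named probes kept their direction under each alternative that tested them, and 3 of the 4 passed the adjusted threshold with the replicate block and without sham replicate 2. The 3′ Gapdh probe turned from -0.11 to 0.12 with normexp and 0.084 with the percentile over all noncontrol probes or the median, and was -0.35 with quantile normalization and -0.25 with the deposited values (-0.197 to -0.0026 on leaving out each array). The 5′ Gapdh probe turned from 0.10 to -0.050 with the slide as a block (-0.050 to 0.199 on leaving out each array), and the 5′ Pgk1 probe from -0.03 to 0.16 with the percentile over all noncontrol probes or the median, 0.15 with quantile normalization, 0.13 with the deposited values and 0.10 with the slide as a block (-0.129 to 0.102 on leaving out each array). Scan date as a block was not run, since all arrays were scanned on 1 day and the scan times followed the slides. Gene list alternatives were not run for want of gene symbols. Signal near background limits the dim probes, whose folds shrank under normexp.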

Other observations

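The tests of the repeat families, the comparison with matched lists included, and of the control probes were all chosen after the data were seen.

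Probes that share sequence with B2, a short interspersed repeat that occurs in many rodent transcripts, had a higher median signal on each SAH array than on each sham array, and none passed the adjusted threshold. A B2 consensus written from general knowledge, not taken from the files, shared at least 14 bases in a row with 35 probes, of which 29 were tested, and its reversed sequence with 0. The median normalized signal of the 29 was 6.41, 6.37 and 6.29 on SAH replicates 1, 2 and 3 and 5.73, 6.25 and 4.34 on sham replicates 1, 2 and 3, a difference of 0.92 on the log2 scale (exact permutation test, two-sided, p = 0.1, the smallest possible). The nearest values, 6.29 on SAH replicate 3 and 6.25 on sham replicate 2, almost met, so the separation of the groups is slight. Of the 29 probes, 28 had a difference above 0, 25 had no overlap between groups and 0 passed the adjusted threshold. The difference fell to 0.37 without sham replicate 3 and was 0.65 with quantile normalization and 1.11 with the percentile over all noncontrol probes.

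A hypothesis is that B2-bearing RNA in plasma exosomes may be higher after SAH. Probes of the same brightness shifting alike would be a technical source, and the median difference per probe, 0.99, lay at percentile 99.99 of 10000 random lists matched on mean signal, whose central 95% ran from -0.17 to 0.59. The 29 probes share sequence and can bind the same RNA, so they are not independent, and the size rests largely on sham replicate 3. Of the B1, B2 and ID families, 4 lists by family and strand held enough tested probes. The B2 antisense list of 17 probes differed by 0.17 in the median of arrays (exact permutation test, p = 0.8) and by 0.76 in the median per probe, at percentile 99.86 of its matched lists. The B1 sense list of 7 probes differed by -0.03 in the median of arrays (exact permutation test, p = 1) and by 0.41 per probe, at percentile 97.4, and the B1 antisense list of 8 probes by 0.56 (exact permutation test, p = 0.1) and 0.63, at percentile 97.2. Both B1 lists lay within the central 95% of their matched lists, with upper limits of 0.414 and 0.643, and the B2 antisense list lay above its own, 0.46.

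The number of probes well above background followed the signal of 25 control probes named ERCC or ETG, with Pearson's r of 0.961 (exact permutation p = 0.00694) and Spearman's rho of 0.943 (exact permutation p = 0.0167) over 6 arrays. Without the 2 arrays farthest from the median control signal, sham replicate 3 and SAH replicate 3, r was 0.644 over the other 4, so the relation rests in part on those arrays. Within the slide of 5 arrays r was 0.986. This was the only relation across arrays computed.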
